A study of Homo sapiens with 8 samples.

How the data were processed

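Chromatin immunoprecipitated with antibodies against HCAR1, a cell-surface receptor for lactate also called GPR81, was sequenced from primary human lung cells (ChIP-seq). The 8 libraries came from 4 cultures of cells sorted as positive for CD44 and SSEA4, each kept without lactate and with 4 mM lactate. Groups and replicate numbers were taken from the labels, which give both libraries of a culture one name and number. The labels call the cells lung cancer cells and also use the abbreviation IPF, whose meaning they do not give. The extraction label names an mRNA kit although the molecule label says genomic DNA.

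The deposited count table holds read pairs per consensus peak, per the file headers counted with featureCounts, without strand, from primary alignments with both ends mapped, leaving out marked duplicates. The submitters' processing notes name Trimmomatic 0.39, BWA 0.7.17, Picard 3.0.0, SAMtools 1.14, MACS2 2.2.7.1, featureCounts 2.0.5 and the genome build GRCh38.p13. Peak lists were deposited for the 4 lactate libraries, 1 list per library, so no peak was chosen in an untreated library. Each list gives, as the authors' values, a fold enrichment (a ratio to the peak caller's background) and the −log10 of a p-value and of a q-value. The peak caller's background sample and settings are not given in the sources used here. The deposited consensus peaks, whose names point to the tool MSPC, carry a −log10 p-value per the file headers. For 420 of the 420 peaks found in 1 list, this number was within 0.001 of that list's −log10 q. The deposited table named CPM holds log2 values. They equalled edgeR's log2 CPM with TMM scaling over all 431 peaks and a prior count of 1, with a largest difference of 0 at 6 decimals. The table therefore carried no library total beyond the sum of the peak counts, and whole-library depth is unknown.

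Sites were compared between lactate and untreated libraries with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, filterByExpr, two-sided, Benjamini-Hochberg adjusted p under 0.05) in R 4.3.3, with all 8 libraries and no covariate. This design, the rule for named sites and the alternatives were fixed before the data were examined, except for 5 alternatives added afterwards, which the account of processing effects names. DESeq2 1.42.0 and limma 3.58.1 were alternatives. Others were median-ratio scaling, column sums, other count filters, the culture as a block, and leaving out libraries or whole cultures. Summed read pairs, and the median over sites of the difference in log2(CPM + 1), were compared with exact permutation tests over the 70 splits of 8 libraries, two-sided, whose smallest p is 0.0286. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used. The pairing rests on the labels, which give same-numbered libraries one culture. As a check, deviations from the group means over the tested sites correlated at 0.62 to 0.84 in 3 of the 4 pairs. The other pair, culture 3, was at −0.34. Pairs of different cultures ranged from −0.84 to 0.72, the latter for untreated replicate 4 with lactate replicate 3, with a mean of −0.18.

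The edgeR step was tested on simulated counts drawn from the real means and library sizes, with 4 changed sites in each of 20 simulations per fold. With 1 common dispersion and any site allowed to change, 6.25% of the changed sites were recovered at 1.5-fold, 10% at 2-fold and 81.25% at 4-fold, with 5, 3 and 22 false calls. A simulation added after that result was seen gave each tested site its own dispersion and left the strongest site unchanged. It recovered 8.75%, 41.25% and 76.25%, with 2, 3 and 10 false calls. With no count filter and 200 changed sites among all sites, the first simulation recovered 0, 26 and 57 at 2-, 4- and 8-fold, with 0, 5 and 35 false calls. The second recovered 0, 11 and 88, with 0, 2 and 13 false calls. The permutation test called 97% of 200 simulated shifts of 4 SD and 3.5% of simulations without a shift. Such a shift is large, since the pooled SD of log2 summed in-peak read pairs was 0.54. Smaller shifts were not simulated, so the test's power for them is unknown.

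Sites with a mean of at least 50 read pairs over the 8 libraries are called strong here, a threshold set after the counts were seen. Peaks were named by the gene whose body they overlap, otherwise by the nearest gene, with a gene table of assembly GRCh38.p14. That table has no strand and no genome sequence was used. Promoters, exons, introns, GC content and repeats were therefore not analysed here, although planned, and gene bodies took the place of transcription start sites. Gene-body overlap was compared with 1000 seeded placements by bedtools 2.31.1 within the gene-covered span of each chromosome. Assembly gaps were not excluded, which lowers the random share. The naming rule took, per direction, the 10 sites with the smallest p, the 10 with the highest mean CPM, the sites in at least 3 lists, and sites within 10 kb of a gene of the 14 gene lists. Lists overlapped where peaks shared at least 1 bp. Levels of single libraries at sites on the sex chromosomes are not reported.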

Results

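HCAR1 ChIP-seq was compared between 4 untreated and 4 lactate-treated libraries of primary lung cells, 1 of each per culture. The series title concerns movement of the receptor into the nucleus. The count table held 431 consensus peaks with a median width of 122 bp and a range of 71 to 416 bp. Read pairs inside these peaks numbered 41640, 29401, 22073 and 69680 in untreated replicates 1 to 4. They numbered 38828, 33638, 34985 and 51104 in lactate replicates 1 to 4. One read pair thus corresponded to 14.4 to 45.3 CPM of the in-peak total.

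A small number of sites held nearly all of the in-peak read pairs in both conditions. The 15 strong sites took 98.6% ± 0.62 of the in-peak read pairs without lactate and 97.4% ± 1.95 with lactate (SD, n = 4 each). The strongest lay in SNHG14, a long noncoding transcript that hosts small nucleolar RNAs (chromosome 15, 25292094 to 25292509, GRCh38.p13). It took 53.5% ± 6.68 of in-peak read pairs without lactate and 50.7% ± 1.03 with lactate (SD, n = 4 each), a difference of −2.81 percentage points (exact permutation p = 0.429, two-sided). A site in IKBIP (chromosome 12, 98631590 to 98631713) took 15.2% ± 1.84 and 15.8% ± 1.69. A site in the noncoding gene LOC112268123 (chromosome 14, 34542666 to 34542767) took 7.34% ± 0.84 and 7.84% ± 0.31. Of the 15 strong sites, 12 overlapped a gene body and 8 of these a protein-coding one. The authors' fold enrichments at the strong sites were 1.30 to 3.69. The background of these ratios is not given in the sources used here, so they need not be enrichment over input. No input or control-antibody library was among the libraries, so whether these sites are HCAR1 binding was not tested.

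**Figure D1:**
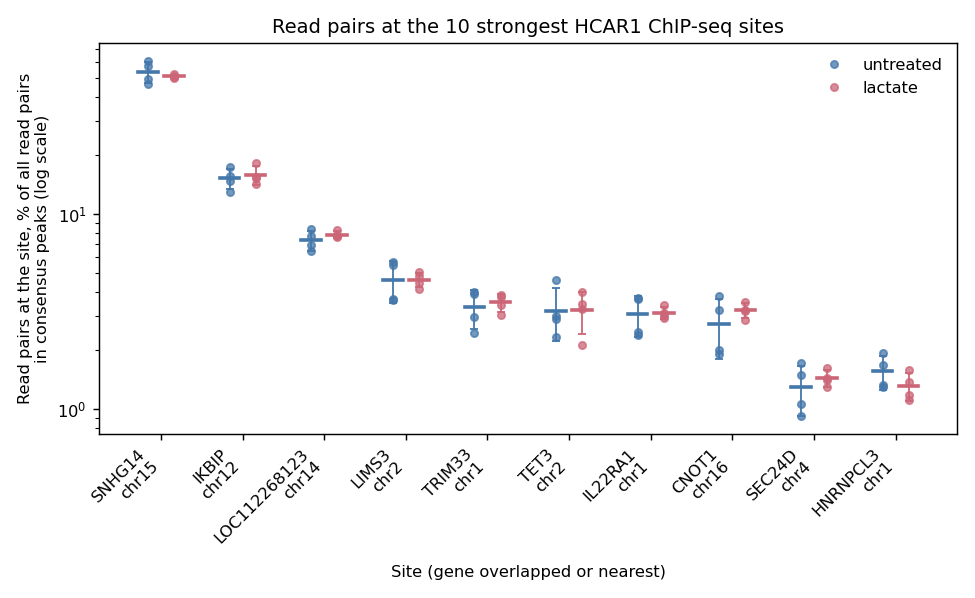
Read pairs at the 10 strongest sites as a percent of all read pairs in consensus peaks, on a log axis, for untreated (blue) and lactate (red) libraries. Points are libraries, horizontal lines are means and error bars are SD (n = 4 per group). The SNHG14 site had means of 53.5% and 50.7%.

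No site differed between lactate and untreated libraries past the threshold. edgeR's quasi-likelihood test called 0 of 19 tested sites, the smallest Benjamini-Hochberg adjusted p was 0.984, and 0 sites had an unadjusted p under 0.05. DESeq2 also called 0, with 0 at an unadjusted p under 0.05. With the culture as a block, 0 sites were called and 1, next to HNRNPCL3, had an unadjusted p under 0.05 (edgeR, log2 fold change −0.33, adjusted p = 0.528). As a share of in-peak read pairs it was lower with lactate in 4 of 4 cultures, a count made after its value was seen. It was the only 1 of the 19 tested sites with one direction in all 4 cultures, where chance gives 12.5% of sites, or about 2.38. The count filter left the other 412 peaks out of this fit. Without a filter edgeR tested all 431 peaks and called 0 (smallest adjusted p = 0.562). In both simulations that fit recovered 0 of 200 sites changed 2-fold, so it cannot exclude changes of that size.

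The strong sites, none of which passed, are given as log2 fold changes of lactate over untreated with edgeR standard errors. The site next to HNRNPCL3, a member of the hnRNP C-like family (chromosome 1, 13063345 to 13063457), was at −0.36 (SE 0.21). CNOT1, which encodes the scaffold of the CCR4-NOT deadenylase, had a site at 0.19 (SE 0.15) on chromosome 16, 58602617 to 58602724. The SNHG14 site was at −0.20, with a 95% interval of −0.60 to 0.20, and ranged from −0.33 without culture 1 to −0.041 without culture 3. SEC24D, a component of the COPII vesicle coat, had a site at 0.10 (SE 0.15) on chromosome 4, 118787916 to 118788047. The site nearest to TMEM47 was at −0.21 (SE 0.34). The site in SOD2, the mitochondrial superoxide dismutase gene (chromosome 6, 159702901 to 159702989), was at −0.13 (SE 0.31). Sites in LIMS3, SH3PXD2B, IKBIP and IL22RA1 were at −0.068, −0.067, −0.057 and −0.049. The site in TET3, which encodes an enzyme that oxidises 5-methylcytosine (chromosome 2, 74113739 to 74114106), was at −0.053 (SE 0.18). The site nearest to TRIM33 was at 0.0082 and that in LOC112268123 at 0.0060. The noncoding LOC102724848 was at 0.20 (SE 0.36). The MTRNR2L12 site had the widest interval of the strong sites, −1.75 to 1.75.

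Among the 15 strong sites, 5 had positive and 10 negative estimates, from −0.36 to 0.20. For 14 of them the 95% interval lay within 1 log2 unit of 0, and for 9 within 0.6. The 4 other tested sites had few read pairs. LOC105375341 was at 0.52 (SE 0.82), CEP128 at 0.38 (SE 1.12), the site next to CDC27P11 at −0.37 (SE 1.03) and that nearest to LOC101929814 at −0.022 (SE 0.68). Reads from near-identical copies may be split at LIMS3, HNRNPCL3 and MTRNR2L12, which would make their values uncertain. Whether reads map to a single place there was not tested.

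The summed read pairs did not separate the groups either, but whole-library depth is unknown, so the sums mix depth with binding. They cannot show whether binding as a whole changed. The mean log2 of in-peak read pairs was 15.18 without and 15.25 with lactate, a difference of 0.078 (exact permutation p = 0.857, two-sided), with 2 of 4 cultures higher. The median site was 0.95 higher with lactate on the log2(CPM + 1) scale (exact permutation p = 0.571, two-sided), and 330 of 431 sites were higher. All 431 sites were chosen in lactate libraries, 384 of them only in replicate 3, which favours higher values with lactate. Untreated replicate 3 also had 0 read pairs at 343 sites, against 75 to 157 sites in the other untreated libraries, which lowers the untreated mean. The test cannot separate a shift from this choice or from these 0 values. Leaving out culture 3 removes lactate replicate 3 and untreated replicate 3 together. Without culture 3 that median was −0.21 and 189 sites were higher, and without the weak sites listed only by lactate replicate 3 it was 0.29. With the deposited log2 CPM, which differ both in TMM scaling and in the count added before the logarithm, it was 0.19, with 275 sites higher. With a pseudocount of 50 and no TMM scaling it was 0.34. The log2 TMM factors over all sites averaged 0.42 higher with lactate, and −0.013 without lactate replicate 3.

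The peak lists differed in length and shared few sites. They held 22, 21, 1392 and 38 peaks for lactate replicates 1 to 4, each called by the authors in 1 library. The lists formed 1458 regions, of which 11 were in at least 2 lists, 4 in 3 and 0 in 4. The 4 consensus peaks in 3 lists were those at SNHG14, IKBIP, TET3 and HNRNPCL3. The list of replicate 2 overlapped none of the others. It lacked the SNHG14 and IKBIP sites, where lactate replicate 2 had 17019 and 6139 read pairs. Absence from a list therefore does not show absence of reads, and the peak caller's background is not known. Of the 431 consensus peaks, 384 were only in the list of replicate 3, or 89.1% (95% Wilson interval 85.8 to 91.7%, counting error only). At a −log10 q of at least 5 the lists held 5, 1, 24 and 8 peaks.

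The 380 weak sites listed only by lactate replicate 3 averaged 4.86 read pairs per site in that library and 1.21, 1.13 and 1.30 in lactate replicates 1, 2 and 4. Untreated replicates 1 to 4 averaged 1.85, 1.17, 0.216 and 1.80. At the 35 weak sites outside list 3 they had 153, 41, 60 and 54 read pairs in all, so untreated replicate 3 was not the lowest there. Of the 380 sites, 73.7% had 4 or 5 read pairs in the library that listed them. Their summed read pairs were 0.84 log2 units higher with lactate (exact permutation p = 0.514, two-sided). That difference includes the library in which the sites were chosen, and the choice raises it. Without culture 3 the difference was −0.38, and 0 of the other 3 cultures were higher; 3 against 3 libraries cannot reach p under 0.05.

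**Figure D2:**
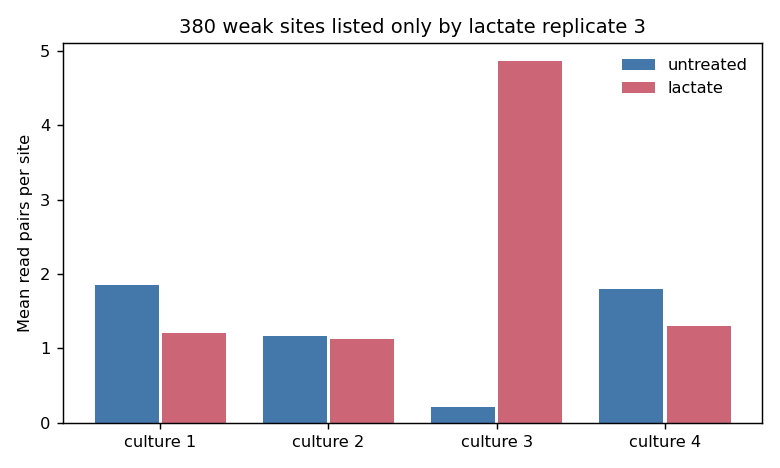
Mean read pairs per site in each library over the 380 weak sites listed only by lactate replicate 3, by culture, untreated (blue) and lactate (red). Each bar is 1 library, so there are no error bars. Culture 3 stood at 0.216 without and 4.86 with lactate. The sites were chosen for being high in lactate replicate 3, which raises its bar. If untreated replicate 3 was the peak caller's background, which is unknown, the choice also favoured sites low in that library.

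Gene bodies held 68.0% of the consensus peaks, against 55.4% ± 2.39 (SD) for randomly placed peaks (permutation p = 0.002, two-sided, the smallest that 1000 placements can give). Protein-coding gene bodies held 52.7%, against 41.8% for random placement. Most of the peaks, 384 of 431, were only in the list of lactate replicate 3. Without them gene bodies held 74.5% of 47 peaks, against 55.3% ± 7.09 (SD) for random placement (permutation p = 0.01, two-sided). Assembly gaps were not excluded, which lowers the random values. Whether mapped reads in general show the same excess was not tested.

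Sites were also sought near genes of the lists for lactate metabolism, hypoxia, stem-like state and related themes. Of 14 lists with 327 genes, 6 had a site within 50 kb of a gene, 8 sites in all. Of these sites, 5 were listed only by lactate replicate 3. The number that chance would give was not worked out, so the counts show neither an excess nor a lack. No list had enough tested sites for a set test. Sites lay inside SLC16A7, which encodes a monocarboxylate transporter that carries lactate, EPAS1, which encodes a hypoxia-inducible factor, and MDM2, which encodes a ubiquitin ligase for p53. The SLC16A7 site (chromosome 12, 59746434 to 59746526) had 2 read pairs over the untreated and 6 over the lactate libraries, 4 of them in replicate 3. The EPAS1 site (chromosome 2, 46386198 to 46386322) had 7 and 13, of which 7 were in lactate replicate 3. The MDM2 site (chromosome 12, 68850448 to 68850597) had 2 and 10, of which 7 were in lactate replicate 2. Further sites lay near LDHB, PFKM, PGAM1, WT1 and ribosomal RNA genes. The lists for stem-like state, epithelial to mesenchymal transition, extracellular matrix and fibrosis, cell migration, ribosome and translation, histones, lung epithelium and immune cells had 0 sites. The count filter left the SLC16A7, EPAS1 and MDM2 sites out of the main fit. edgeR without that filter called 0 of 431 sites, but in both simulations it recovered 0 of 200 sites changed 2-fold. The SLC16A7, EPAS1 and MDM2 sites were each chosen in a lactate library, which favours higher sums with lactate.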

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

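All tests of causes in this part were chosen after the results were seen, except those of the count of called sites and of a shallow untreated library. Of 43 groups of 4 libraries examined, 8 held a library far from the others, where chance gives about 1 in 20 for independent groups. The groups share the same libraries, and several of the 8 follow from the choice of sites. The count therefore cannot be set against that rate.

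The list of lactate replicate 3 held 1392 peaks against 21 to 38 in the others, and that library had 1846 read pairs at the 380 weak sites it alone listed, against 428 to 494 in the other lactate libraries. The sites were chosen for being high there, so the second value repeats the first. A gain with lactate at these sites in every culture, by a mean above 1 log2 unit relative to the strong sites, is argued against by replicates 1, 2 and 4. There the log2 ratio of lactate to untreated at these sites, relative to the strong sites, averaged −0.27 (SD 0.25). A gain shared with the strong sites would cancel in this ratio, and gains at other sites were not covered. In culture 3 the ratio was 3.90, a value raised by the choice of sites. Culture 3 was also the pair at −0.34 in the check of the pairing. Chance pile-ups may account for the list, but 5.0% of the sites reached 4 read pairs in the other 3 lactate libraries on average, which lies at, not under, the bound of 5%, and a response in culture 3 alone predicts a low share too. A shallow untreated library of culture 3 cannot be told apart from these: at the 35 weak sites outside list 3 it had 60 read pairs, under the bound set beforehand, which was below 50% of the median of 137 in the other 7 libraries. That bound counted lactate libraries in which those sites were chosen, and against the other untreated libraries alone, a comparison added after the value was seen, 60 lay above the median of 54.

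The TMM factor over all sites was 2.83 in lactate replicate 3, against 0.781 to 1.03 in the other lactate libraries. Without the weak sites listed only by that library the factor was 1.02, consistent with the choice of most sites in it as the source. At the strong sites it had 33077 read pairs and the other 3 averaged 40555 (SD 8955). A shortfall to below 50% of that mean, or 20278, is argued against, since the value lies 12800 above this bound, more than the SD. A smaller shortfall stays open. In the untreated group the factor of replicate 4 was 0.565, against 0.973 to 1.02, and without the same weak sites it was 0.957.

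The other distant libraries are given as values. The site next to CDC27P11 took 0.154% of in-peak read pairs in untreated replicate 1 and 0.00718 to 0.0238% in the other untreated libraries. MTRNR2L12 took 0.716% in lactate replicate 2 and 0.104 to 0.197% in the other lactate libraries. LOC105375341 took 0.0800% in lactate replicate 3 against 0.0446 to 0.0489%. LOC112268123 took 8.30% in lactate replicate 2 against 7.65 to 7.74%.

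For the count of called sites, the comparison with other splits decides nothing about chance: the real grouping called 0 sites, so 35 of 35 splits of the 8 libraries gave at least as many by construction. The highest other split gave 4. Only 3 splits called any site, and 1 of them set cultures 1 and 4 against 2 and 3, with 3 calls. Of the 8 splits that part every culture's pair, the real one included, 0 called a site.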

How the results depend on the processing

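The settings without the weak list-3 sites (for called sites, summed read pairs and the median site), with pseudocount 50 and with deposited TMM-scaled values as the site median were chosen after seeing the data. The count of called sites was 0 under all 25 alternatives, with smallest adjusted p from 0.179 to 0.992. At an unadjusted p under 0.05 there were 9 of 431 sites without a filter, 6 of 431 with limma, and 19 of 393 for the sites of list 3 tested without culture 3. There were 2 without untreated replicate 4, 2 without culture 4, and at most 1 elsewhere. With the replicate block 0 sites were called, the smallest adjusted p was 0.528, the log2 read pair difference stayed 0.078 (sign-flip exact p = 0.75) and the median site 0.95 (exact p = 1.0); the block changed no call, and 16 flips cannot give p under 0.125.

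Summed read pairs with lactate minus untreated ranged from −0.12 to 0.25 without each culture, the lowest without culture 3. Without the 1% of peaks with most reads the difference was 0.23 (exact permutation p = 0.714, two-sided). The planned sum of deposited CPM gave −0.41, but these values are scaled to the in-peak total and hold no read pair totals, so it reflects the TMM factors. The median site ranged from −0.21 to 2.02 without each culture, the lowest without culture 3. Regions in at least 2 lists numbered 4 to 11 without each list, 4 without replicate 3 and 5 without replicate 4. The share of consensus peaks only in list 3 was 3.94% of all 431 at a −log10 q of at least 5, where 404 were in no list and 17 of the other 27 (63.0%) only in list 3. It was 0 to 90.5% without each list, 0 by construction without list 3. Sites near listed genes fell from 8 to 3 with a 10 kb window.

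Of 112 estimates for named sites, 11 had another sign, at 10 sites. With the replicate block MTRNR2L12 was at 0.028 and CDC27P11 at 0.058. Without each culture in turn, IL22RA1 ranged from −0.051 to 0.010, LOC101929814 from −0.18 to 0.24, TET3 from −0.17 to 0.037, LOC102724848 from −0.13 to 0.49, MTRNR2L12 from −0.18 to 0.20, SOD2 from −0.28 to 0.015, LOC105375341 from −0.062 to 1.30, IKBIP from −0.080 to 0.041 and CEP128, not tested without culture 4, from −0.14 to 0.49. CDC27P11 was not tested without culture 1. None was called, and the cause was not tested. Promoter width, blocked or correlated set tests, and CPM-implied totals, which equal the column sums, were not run. Whole-library depth is unknown, and means of 0.216 to 4.86 read pairs per weak list-3 site limit what could be seen.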

Other observations

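The test in this part was chosen after the pattern was seen. The MTRNR2L12 site, in a nuclear gene related to the mitochondrial 16S ribosomal RNA, was in the list of lactate replicate 2 alone. It had 158 read pairs in untreated replicate 2 and 241 in lactate replicate 2, against 48 to 55 and 42 to 69 in the other untreated and lactate libraries. The CNOT1, SH3PXD2B, SOD2 and LOC102724848 sites, among the strong ones, were in the list of lactate replicate 3 alone, although all 15 strong sites had at least 42 read pairs in every library, untreated ones included.

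At the strong sites the authors' fold enrichments had a median of 2.08 (1.30 to 3.69), and at the other sites 4.66 (4.15 to 16.8). Only peaks past the caller's cut are listed, and with few read pairs a site passes it only at a high fold. The contrast therefore does not show stronger enrichment at the weak sites. Within the lists these folds tended to follow the ratio of lactate to untreated read pairs of the same culture. A candidate explanation is that the untreated library of the same culture was the background of the peak calling, but the values below restate the pattern and give it no independent support. In the 3 lists with at least 5 strong sites, Spearman's rho across sites, which are not independent, was 1.0 (5 sites), 0.732 (14) and 0.533 (9) with the same culture, a mean of 0.755. It was the highest of the 4 untreated libraries in each list. Pearson's r on log2 values was the highest in 2 of the 3 lists, and for the list of replicate 3 was 0.696 with its own culture and 0.750 with untreated replicate 2. The list of replicate 2 lacked the SNHG14 and IKBIP sites although lactate replicate 2 had 17019 and 6139 read pairs there. Untreated replicate 2 had 16890 and 4608, so a background as high as that library could leave these sites out. A separate input library of the same culture that was high at both sites could do the same. The question therefore stays open.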
